A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

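The samples were 12 libraries of Saccharomyces cerevisiae, 3 immunoprecipitates of FLAG-tagged Rpb3 and 3 inputs for each of 2 strains, wild type and dbp2Δ, described in the labels as biological replicates. Cells were fixed with formaldehyde and the chromatin sonicated, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 2.3.3.1, MACS2 2.1.2 and genome build R64. The trimming and alignment settings were not given in the sources used here.

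Per the file headers, the authors called peaks once per strain with MACS 2.1.2 in paired-end mode, on the 3 pooled immunoprecipitates against the 3 pooled inputs. The q-value cutoff was 0.05, the effective genome size 12000000, 1 duplicate was kept per position, and the local background was taken over windows of 1000 and 10000 bp. The recorded fragment size was 260 bp in the wild type and 290 bp in dbp2Δ, and no peak was shorter than this size in its list. Redundant fragments made up 10% and 11% of the immunoprecipitates and 2% of either input. The deposited lists give each peak's start, end, length in bp and summit, counted from 1 as in a genome browser. Each peak's pileup, the coverage signal at its summit as the authors' caller gave it, was not compared between the lists. The deposited −log10 q-values were not used for any comparison. The fold enrichment is a ratio of the immunoprecipitate to the local background at the summit, per the file headers, and was used to describe, rank and filter peaks within a list. Because the pooling took place before the peaks were called, values per replicate were not analysed here, and leaving out single replicates or pairing them was not possible. No p-value for a difference between the strains was computed, and the shares of random lists given below are tail shares over genes.

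Genes were taken from a RefSeq table of assembly R64, the build named for the peaks, with 6431 genes on the 16 nuclear chromosomes, 6002 of them protein-coding. The 46 mitochondrial genes were left out because neither list held a mitochondrial peak. The protein-coding gene lengths were multiples of 3 for 96.3% of genes, so they were taken as spans of the coding region without UTRs. These spans include any introns, and distances past a gene end include the UTR. The strand was read from the W or C letter of the systematic name. The table holds no exons, so a planned list of intron-containing genes was not analysed here, and peaks were not divided into exonic and intronic. The length of each chromosome was taken as its highest annotated or peak coordinate, 12055562 bp in sum.

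A gene had a peak when at least 50% of its length was covered. The fold enrichment given for a gene is that of the highest peak overlapping any part of it. It can therefore reflect signal of a neighbouring gene. Peaks were shared when they overlapped by at least 1 bp. The overlap of the lists was compared with 1000 random placements of the dbp2Δ list, each shifting its peaks together around each chromosome by a random distance. Gene groups were fixed before the data were examined, as were the comparisons and the rule for the named genes. The groups were cytosolic ribosomal protein genes, glycolysis, translation factors, ribosome biogenesis, chaperones, hexose transporters, galactose genes, glucose-repressed genes, methionine and sulfur genes, other amino acid biosynthesis, phosphate starvation, the iron regulon, histones, cell wall and plasma membrane, a-specific and alpha-specific genes, meiosis, genes with premature termination control, mRNA export and packaging factors, Pol II subunits, subtelomeric cell-surface genes, snoRNA, snRNA, tRNA, other Pol III and rRNA genes. Symbols without a match in the table left 51 of 52, 4 of 6, 11 of 12 and 19 of 20 members in the other amino acid, alpha-specific, premature termination and mRNA export groups. Each protein-coding group was compared with 10000 random lists of the same size matched on deciles of gene length, and non-coding groups with 1000 sets of intervals of the same lengths placed at random on the same chromosomes, with the peaks kept in place. Loss among genes with a wild-type peak was also compared with 10000 random lists matched on 5 bins of wild-type fold enrichment, and for the planned groups with 10000 shuffles of the lost genes among genes of similar fold enrichment, both added after the values were seen. These comparisons describe the lists and carry no error between replicates.

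Peak position was measured on protein-coding genes with exactly 1 peak over at least 50% of the gene in each strain, where that peak covered at least 50% of no other gene. Edge differences were taken along the direction of transcription, positive outward, dbp2Δ minus wild type. Summit position was a percent of gene length from the 5′ end. Medians were given 95% intervals from 10000 bootstrap resamples over genes, and shares Wilson 95% intervals, both over genes and not over replicates.

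The genes named are the deleted, marker and tagged loci, the genes of the 12 highest peaks and of the 10 highest strain-specific peaks per list by fold enrichment, up to 4 members per group with the highest wild-type fold enrichment, up to 4 members per group with a peak in 1 strain only, and the 5 genes with the largest 3′ edge difference in each direction. For the strain-specific peaks, genes at least 50% covered were named, otherwise genes overlapped, otherwise the nearest. Where a short count was listed in full, the names beyond this rule were LEU1 and HIS4 in the amino acid group, VTC4 in the phosphate group, and the uncovered non-coding genes. They were chosen after their values were seen.

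The procedure was run on simulated peak lists of 1309 genes, where it recovered 60 of 60 planted wild-type-only and 80 of 80 planted dbp2Δ-only peaks. Among the genes measured it recovered 192 of 192 planted 3′ shifts of 300 bp, with 0 genes called shifted without a planted shift. The simulated lists were identical apart from the planted changes and held no noise. Full recovery therefore checks the calculation only, and says nothing on small shifts or noisy peaks. Alternatives tried were a minimum fold enrichment of 2, the same number of highest-fold peaks per list (1221), joining of nearby peaks, other overlap and coverage rules, other thresholds of shift, and subsets of genes by neighbour, length and peak height. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.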

Results

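Chromatin immunoprecipitation followed by sequencing was used to map RNA polymerase II (Pol II) in budding yeast with and without Dbp2, a DEAD-box RNA helicase. Both strains carried a FLAG tag on Rpb3, a Pol II subunit, and were grown in rich glucose medium. Each strain contributed 3 immunoprecipitated and 3 input libraries, 12 in all. The depth recorded for the pooled immunoprecipitates was 4073418 fragments in the wild type and 4551809 in dbp2Δ, of which 3648848 and 4030024 remained after duplicates were removed. The pooled inputs held 5106431 and 4748970 fragments after the same step. The results are 1 list of peaks per strain, called on the pooled libraries, so no spread between replicates could be computed and no test between the strains was possible. Differences between the lists are therefore described with their spread over genes or against random gene lists, which is not replicate error.

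DBP2 was examined first because it is the deleted gene. DBP2 (YNL112W, chromosome XIV, 413639 to 416281, R64) was 100% covered by a wild-type peak with a fold enrichment of 5.69, and 0% covered in dbp2Δ, where peaks ended on either side of the gene. The auxotrophic marker genes deleted in the parent strain, HIS3, LEU2, MET17 and URA3, had no peak in either list. RPB3 (YIL021W, chromosome IX, 312905 to 313861), the tagged gene, was covered over 21.9% of its length in the wild type and 14.7% in dbp2Δ, less than the 50% required to count as a gene with a peak. The fold enrichment of a peak is the authors' own value from the peak caller. It ranks peaks within a list, and values of the 2 lists are set side by side without a direction because the lists were scaled separately.

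**Figure D1:**
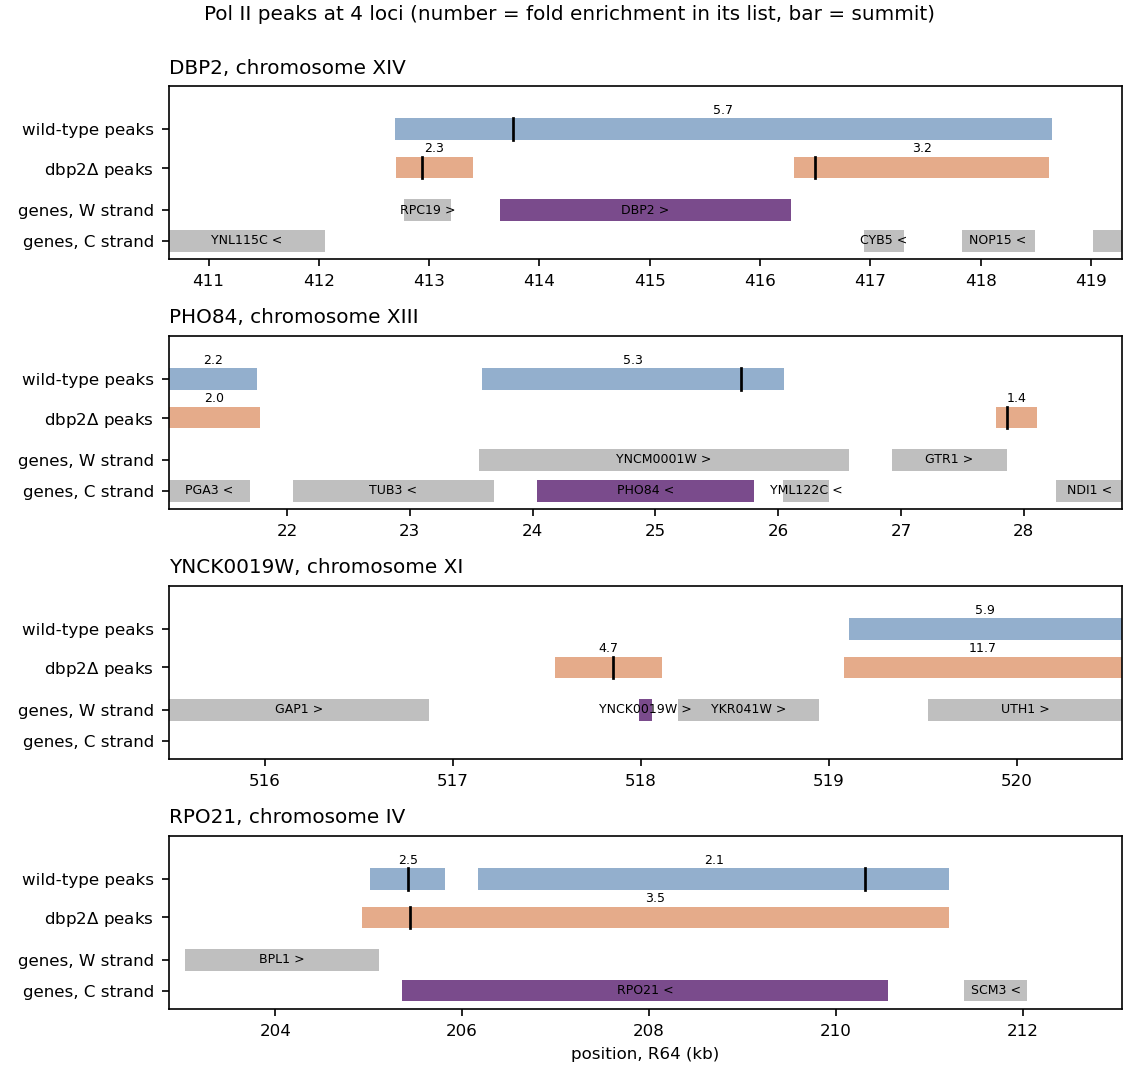
Peaks of the wild-type list (blue) and the dbp2Δ list (orange) along the chromosome (kb, R64) at DBP2, PHO84, the tRNA gene YNCK0019W and RPO21, with the fold enrichment above each peak, summits as black bars and genes below by strand. DBP2 and PHO84 were covered in the wild type only, YNCK0019W in dbp2Δ only, and at RPO21 the wild-type peak with its summit near the 5′ end of the gene (4.83% of its length) had a longer counterpart with its summit near the 3′ end (98.5%).

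The first comparison asked where Pol II peaks lay in each strain. The 12 highest peaks of both lists included genes of small nucleolar RNAs, ribosomal proteins, translation elongation factors and a cell wall protein, beside other loci. In the wild type the highest peak covered the snoRNA genes SNR128 and SNR190 with RPA34 (chromosome X, 139047 to 141579, fold enrichment 19.5). It was followed by the peak over YDR524W-C, YDR524C-B and API2 (chromosome IV, 1488570 to 1490123, 19.2), RPL33B with IRC13 and SNR17A (19.2), and AHP1 with CCW12 (17.7), CCW12 encoding an abundant cell wall mannoprotein. The remaining peaks of the first 12 covered SNR30 (16.2), TEF2 (15.7), PAM16 with SNR37 (15.5), PCL1 with SNR40 (15.5), TEF1 (15.3), RPL28 with YGK1 (15.3), SNR10 with YGL088W and MMS2 (15.3), and SNR8 with YTM1 (15.0).

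In dbp2Δ the highest peak lay over AGE1, YDR524W-C, YDR524C-B and API2 (chromosome IV, 1488254 to 1490080, 19.6), followed by AHP1 with CCW12 (19.5), TEF2 (17.4) and RPS14B with RPS22A and RPL39 (17.1). TEF1 (16.5) and the locus of SRG1, SER3 and UTP7 (chromosome V, 321945 to 326465, 16.4) came next, SRG1 being the non-coding RNA transcribed across the SER3 promoter. The others of the first 12 covered SNR8 (15.9), RPL33B with IRC13, SNR17A and DFR1 (15.7), RPL28 with YGK1 (15.5), RPS31 with UPS2 (15.2), RPS9A with YPL080C and RPL21B (15.2), and RPL9B with SUN4 and YNL067W-B (15.0). Of the 12 highest wild-type peaks, 7 overlapped one of the 12 highest dbp2Δ peaks. A snoRNA gene was covered by 7 of the 12 in the wild type and 2 of the 12 in dbp2Δ, and a ribosomal protein gene by 2 and 6.

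The wild-type list held 1642 peaks over 2.24 Mb (18.6% of the mapped genome), with a median width of 886 bp and a median fold enrichment of 1.99. The dbp2Δ list held 1628 peaks over 2.41 Mb (20%), with a median width of 988.5 bp and a median fold enrichment of 2.04. Of the wild-type peaks, 1356 (82.6%) overlapped a dbp2Δ peak by at least 1 bp, and 1285 of the dbp2Δ peaks (78.9%) overlapped a wild-type peak. The lists shared 1.86 Mb, which was 66.5% of their union, against a mean of 10.9% and a maximum of 15.2% over 1000 random placements. When an overlap of at least 50% of both peaks was required, 57.9% of the wild-type and 58.4% of the dbp2Δ peaks were shared.

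Among the peaks present in 1 list only, those with the highest fold enrichment in the wild type covered URA1 (YKL216W, chromosome XI, 24523 to 26689, 5.38), which encodes dihydroorotate dehydrogenase of pyrimidine synthesis, and PHO84 (YML123C, chromosome XIII, 23586 to 26044, 5.35), which encodes the high-affinity phosphate transporter. The PHO84 peak also covered the antisense RNA gene YNCM0001W. Next came BIK1 (3.24), a peak nearest to CSS1 (3.17), YHB1, which encodes the nitric oxide dioxygenase flavohaemoglobin (2.62), and peaks that overlapped WHI5 (2.28), PRY1 (2.22), MNR2 (2.20) and YGL149W with ARO2 (2.17) or covered YHR022C-A (2.17). In dbp2Δ the peak of highest fold enrichment without a wild-type counterpart covered the tRNA gene YNCK0019W (chromosome XI, 517544 to 518113, 4.65), and the next the tRNA gene YNCL0034W (chromosome XII, 628007 to 628580, 4.13). They were followed by a peak over the ends of SGV1 and ORC4 (3.47), SLT2, which encodes the cell wall integrity MAP kinase (3.19), YOL118C (2.81), ARO9 with YHR138C (2.78), DOM34 (2.64), the tRNA gene SUF17 with DIS3 (2.62), and the tRNA genes YNCG0030C (2.54) and YNCD0016C (2.51).

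In total 286 wild-type and 343 dbp2Δ peaks had no counterpart. Of the 286, 41 were shorter than 290 bp, the shortest length in the dbp2Δ list. With peaks of at least 290 bp alone, 245 wild-type and 365 dbp2Δ peaks had none. A tRNA gene was covered by 0 of the 286 and by 13 of the 343 (3.79%), and a protein-coding gene by 47 and 41. Among shared peaks, a tRNA gene was covered by 33 of 1356 (2.43%) in the wild type and 50 of 1285 (3.89%) in dbp2Δ. Peaks without a counterpart had low fold enrichments within their own lists, with medians of 1.59 and 1.55 against 2.16 and 2.28 for shared peaks. Of them, 24 (8.39%) and 31 (9.04%) ranked in the upper 50% of their list. With peaks of at least 2-fold enrichment alone, 124 of 815 wild-type and 155 of 843 dbp2Δ peaks lacked a counterpart.

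The next comparison asked which genes and gene groups carried a peak in each strain. Ribosomal protein genes were covered throughout, with 137 of 137 genes in both lists against a mean of 34.0 for random lists matched on gene length in the wild type. RPL33B (fold enrichment 19.2 in the wild type, 15.7 in dbp2Δ), RPL28 (15.3 and 15.5), RPL36A (14.6 and 11.7) and RPL39 (14.4 and 17.1) had the highest wild-type peaks. Translation factors had a peak for 28 of 30 genes in both strains, led by TEF2 (15.7 and 17.4), TEF1 (15.3 and 16.5), YEF3 (9.59 and 12.8) and EFB1 (9.27 and 7.28). Glycolysis and fermentation genes had a peak for 14 of 19 in both, with ENO2 at 14.4 and 9.99, TDH3 at 13.9 and 9.68, PDC1 at 12.1 and 12.7 and FBA1 at 11.3 and 7.09. None of 10000 random lists reached these counts.

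**Figure D2:**
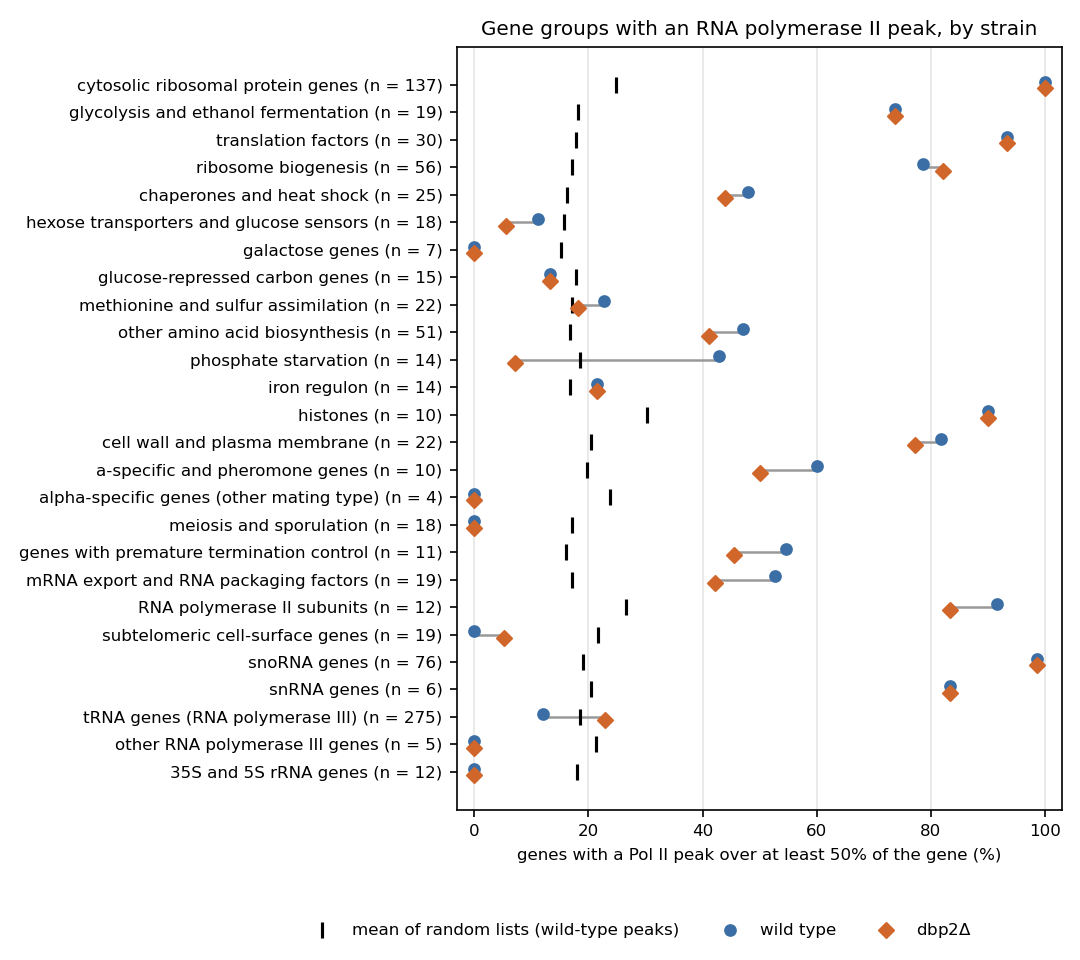
Share of each gene group (%) with a peak over at least 50% of the gene in the wild type (circles) and dbp2Δ (diamonds), with the mean of random lists placed on the wild-type peaks (ticks). Phosphate-starvation genes were at 42.9% in the wild type and 7.14% in dbp2Δ, tRNA genes at 12% and 22.9%, and ribosomal protein genes at 100% in both.

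Ribosome biogenesis genes carried a peak for 44 of 56 members in the wild type and 46 in dbp2Δ, among them RPA34 (19.5 and 14.05), YTM1 (15.0 and 15.9), NOC4 (12.04 and 9.80) and DBP3 (10.1 and 2.65). The values of RPA34 were those of peaks that also covered SNR128 and SNR190, and the values of YTM1 those of peaks over SNR8. NOC4 shared its peaks with ASN1, so these values need not describe the ribosome biogenesis genes themselves. IMP3 (1.82) met the coverage rule in the wild type only, and BMS1, UTP13 and RRP8 in dbp2Δ only, although each of these also overlapped a peak of the other list. Histone genes had a peak for 9 of 10 in both strains, led by HHF2 and HHT2 (6.85 and 5.49) and by HTA1 (6.15 and 4.06) and HTB1 (6.15 and 4.11). Cell wall and plasma membrane genes had a peak for 18 of 22 in the wild type and 17 in dbp2Δ, with CCW12 at 17.7 and 19.5, the proton pump gene PMA1 at 13.0 and 9.63, CWP2 at 9.20 and 10.1 and CIS3 at 9.15 and 12.4. PIR1 met the coverage rule in the wild type only (2.76), with 28.3% covered in dbp2Δ. Chaperone genes had a peak for 12 of 25 and 11 of 25, with SSB1 (7.64 and 8.42), SSB2 (5.68 and 6.47), SSA2 (5.51 and 4.38) and HSC82 (5.14 and 3.55), and SIS1 (1.98, with 28.1% covered in dbp2Δ) in the wild type only.

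Groups that glucose medium or the mating type leaves silent were mostly without peaks, as were most genes. Galactose genes (0 of 7), meiosis and sporulation genes (0 of 18) and the alpha-specific genes of the other mating type (0 of 4) had none in either strain. Random lists matched on gene length had no wild-type peak in 31.8%, 3.04% and 33.0% of draws, so the galactose and alpha-specific counts were not distinguishable from those of random genes. The a-specific and pheromone genes had 6 of 10 in the wild type and 5 in dbp2Δ, with MFA2 (5.76 and 4.37), STE2 (5.59 and 4.06) and MFA1 (3.00 and 2.303) in both and BAR1 (2.82, a peak with its summit outside the gene) in the wild type only. Hexose transporter genes had 2 of 18 and 1 of 18 (44.1% of random lists had at most 2 in the wild type): HXT1 in both (3.46 and 2.47), and HXT3 in the wild type (3.41), with 28.7% of HXT3 covered in dbp2Δ. Glucose-repressed genes had 2 of 15 in each strain (48.5% of random lists had at most 2 in the wild type), ICL1 in both (2.51 and 2.61), MDH2 in the wild type only and CYC1 in dbp2Δ only (1.77). The wild-type peak over MDH2 (8.01) had its summit outside the gene and overlapped a dbp2Δ peak that ended before MDH2. Whether MDH2 had signal of its own within this peak cannot be told from the lists. Subtelomeric cell-surface genes had 0 of 19 and 1 of 19, the latter COS6 (1.46).

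Among the groups of protein-coding genes, the phosphate-starvation genes had the largest difference in the share with a peak. A peak covered 6 of 14 in the wild type and 1 of 14 in dbp2Δ. PHO84 (chromosome XIII, 24037 to 25800, 5.35), SPL2 (chromosome VIII, 374654 to 375100, 2.53), the polyphosphate synthesis genes VTC3 (chromosome XVI, 514511 to 517018, 1.95) and VTC4 (chromosome X, 411234 to 413399, 1.65), and PHM6 (chromosome IV, 1022007 to 1022321, 1.94) had a peak in the wild type and 0% of their length covered in dbp2Δ. VTC1 had a peak in both (4.74 and 3.09). The wild-type peaks of PHO84, VTC3 and VTC4 had no dbp2Δ counterpart, whereas those over SPL2 and PHM6 overlapped a dbp2Δ peak beside these genes. The summit lay outside the gene for SPL2, PHM6 and VTC3, in VTC3 at 517028, next to its 5′ end. The 5 genes were 83.3% of the 6 with a wild-type peak, whereas 15.0% of all protein-coding genes with a wild-type peak had none in dbp2Δ. The count of 5 was 2 when only peaks of at least 2-fold enrichment were used and 8 when any overlap with the gene counted.

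Amino acid biosynthesis genes outside the methionine pathway had a peak for 24 of 51 in the wild type and 21 in dbp2Δ. ILV5 (13.0 and 11.5), ASN1 (12.04 and 9.80) and SER3 (11.9 and 16.4) had the highest wild-type values and a peak in both. The ASN1 values were those of peaks shared with NOC4. The dbp2Δ value of SER3 was that of a peak that also covered SRG1 and UTP7, so it need not describe SER3 itself. ARO2, THR1, SER1, BAT2, LEU1 and HIS4 met the coverage rule in the wild type only. These 6 were 25.0% of the 24 with a wild-type peak, against 15.0% of all protein-coding genes with one, and 6.45% of random lists matched on wild-type fold enrichment lost as many. HIS4 (2.67) was the only one of these 6 with 0% covered in dbp2Δ. The other 5 were partly covered there, over 27.2% of ARO2, 31.1% of THR1, 45.3% of SER1, 12.6% of BAT2 and 39.4% of LEU1. HOM2, HIS6 and LEU4 met the rule in dbp2Δ only. Methionine and sulfur genes had 5 of 22 and 4 of 22, with CYS4 (3.93 and 3.79), MUP1 (3.40 and 4.33), CYS3 (2.65 and 3.20) and SAM1 (2.55 and 3.72) in both and MET6 (2.14, with 5.38% covered in dbp2Δ) in the wild type only. Iron genes had 3 of 14 in both, FET3 (3.01 and 2.23), FRE1 (2.99 and 2.05) and FTR1 (2.53 and 2.00).

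Genes of the RNA machinery were largely shared. Genes under premature termination control had a peak for 6 of 11 in the wild type and 5 in dbp2Δ, with NRD1 (9.68 and 11.1), NAB2 (9.15 and 10.4), IMD3 (8.01 and 10.7) and HRP1 (7.35 and 6.77) in both and ADE12 (4.97, with 21.6% covered in dbp2Δ) in the wild type only. Genes of mRNA export and packaging factors had 10 of 19 and 8 of 19, including SUB2 (8.25 and 7.30) and YRA1 (6.57 and 6.85). The wild-type-only members were DBP2 itself and CBC2 (2.31), of which 41.8% was covered in dbp2Δ. Pol II subunit genes had 11 of 12 and 10 of 12, with RPC10 (4.01 and 2.95), RPB8 (3.05 and 3.23), RPB5 (2.95 and 4.10) and RPB11 (2.94 and 2.37) in both, and RPB7 covered over 50.2% and 21.1%.

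Genes of snoRNAs and snRNAs were covered almost completely in both strains. A peak covered 75 of 76 snoRNA genes in each list, the exception being SNR52, which is transcribed by Pol III. The highest were SNR128 and SNR190 (19.5 and 14.05), SNR17A (19.2 and 15.7) and SNR30 (16.2 and 13.2). Of the snRNA genes 5 of 6 were covered, led by LSR1 (13.2 and 14.4), SNR7-L and SNR7-S (11.1 and 10.8) and SNR19 (9.69 and 8.50), and the exception was SNR6, another Pol III gene. Of the other non-coding RNA genes, 2 of 21 annotated as ncRNA had a peak in the wild type and 1 in dbp2Δ, as did 2 and 1 of 7 antisense RNA genes. The rRNA genes had 0 of 12 and the other Pol III genes (SCR1, RPR1, SNR6, SNR52 and RNA170) 0 of 5 in both lists.

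Genes of tRNAs, which are transcribed by Pol III, were covered more often in dbp2Δ. A peak covered 33 of 275 (12%) in the wild type and 63 (22.9%) in dbp2Δ. The 33 were covered in both lists, 30 had a peak in dbp2Δ only, and 0 in the wild type only, or 2 with peaks of at least 2-fold enrichment. Intervals of the same lengths placed at random on the same chromosomes gave a mean of 51.0 covered by the wild-type peaks, 54.8 by the dbp2Δ peaks and 12.5 by the dbp2Δ peaks only. Of these placements, 99.8% reached the 33 of the wild type, 12.8% the 63 of dbp2Δ and 0% the 30 in dbp2Δ only. The dbp2Δ count was thus not distinguishable from that of random intervals, and the wild-type count was lower than theirs. The tRNA genes with the highest wild-type peaks were YNCP0020W (12.04 and 9.80), YNCG0020C (9.33 and 8.65), YNCE0010W (8.98 and 12.7) and SUF1 (8.98 and 10.01). The summits of these wild-type peaks lay 2206, 1543, 1542 and 597 bp from the tRNA genes, in peaks that covered 1 to 4 protein-coding genes, and the peak over YNCP0020W was that of NOC4 and ASN1. The highest of those covered in dbp2Δ only were YNCL0040W (chromosome XII, 793918 to 793989, 8.98), YNCG0022W (chromosome VII, 541850 to 541921, 8.09), YNCD0007C (chromosome IV, 488797 to 488870, 7.79) and YNCG0023C (chromosome VII, 544577 to 544648, 5.30). YNCG0022W and YNCD0007C were covered over 13.9% and 12.2% in the wild type, and YNCL0040W and YNCG0023C over 0%. The summits of these 4 peaks lay 1164, 7858, 3385 and 763 bp away, in peaks that covered 1 to 3 protein-coding genes, so their fold enrichments describe the whole peak rather than the tRNA gene. Of all 30, 20 had the summit within 150 bp and 16 lay in peaks that covered no protein-coding gene.

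Over all 6431 nuclear genes, 1317 (20.5%) had a peak in the wild type and 1386 (21.6%) in dbp2Δ, 1134 of them in both, 183 in the wild type only and 252 in dbp2Δ only. Of 6002 protein-coding genes, 1197 and 1239 had a peak, with 180 in the wild type only and 222 in dbp2Δ only. When any overlap counted, 2460 and 2698 genes had a peak.

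The last comparison asked where along genes the peaks lay, since Dbp2 has been linked to transcription termination. Of the 1017 protein-coding genes with a peak in both lists, 381 met the rule for measuring position, and the others were not measured. Peaks of the measured genes lay farther toward the 3′ end in dbp2Δ. Among 381 genes with exactly 1 peak over at least 50% of the gene in both lists, the 3′ edge of the peak lay past the end of the gene by a median of 394 bp in the wild type and 453 bp in dbp2Δ. The paired difference had a median of 68 bp downstream (95% bootstrap interval over genes 57 to 76, interquartile range 13 to 124), and 296 genes (77.7%) had the 3′ edge farther downstream in dbp2Δ. A difference of more than 100 bp downstream was found for 134 genes (35.2%, Wilson 95% interval 30.5 to 40.1) and upstream for 28 (7.35%, 5.13 to 10.4).

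The 5′ edges of the same 381 genes lay farther inward. The peak began a median of 176 bp before the gene in the wild type and 134 bp before it in dbp2Δ, and the paired outward difference had a median of -36 bp (-44 to -31). It was below 0 for 294 genes (77.2%).

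Summits were displaced more than edges. The median summit lay at 12.8% of gene length from the 5′ end in the wild type and at 92.2% in dbp2Δ. It lay before the middle of the gene for 251 genes (65.9%) in the wild type and 100 (26.2%) in dbp2Δ, and past the end of the gene for 53 (13.9%, 10.8 to 17.7) and 158 (41.5%, 36.6 to 46.5). The paired difference had a median of 21.7% of gene length (11.6 to 40.9), with 280 genes (73.5%) downstream and 99 upstream. The summits of 149 genes lay within 100 bp of each other in the 2 lists, those of 205 genes lay more than 100 bp farther downstream in dbp2Δ, and those of 27 more than 100 bp farther upstream. Among 51 ribosomal protein genes the median summit lay at 13.7% in the wild type and 109% in dbp2Δ, with a paired difference of 77.6% (59.4 to 104), against 14.8% (7.37 to 26.5) in the other 330 genes. Among 118 genes with peaks of at least 3-fold enrichment in both lists, 51 of them ribosomal protein genes, the 3′ edge difference was 70 bp. The glycolytic gene PGK1 (chromosome III, 137746 to 138996) had its summit at 9.11% and 93.1%, whereas TEF1 (6.46% and 8.35%) and TEF2 (5.74% and 5.59%) had theirs near the 5′ end in both strains. These 3 genes were chosen after their values were seen.

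**Figure D3:**
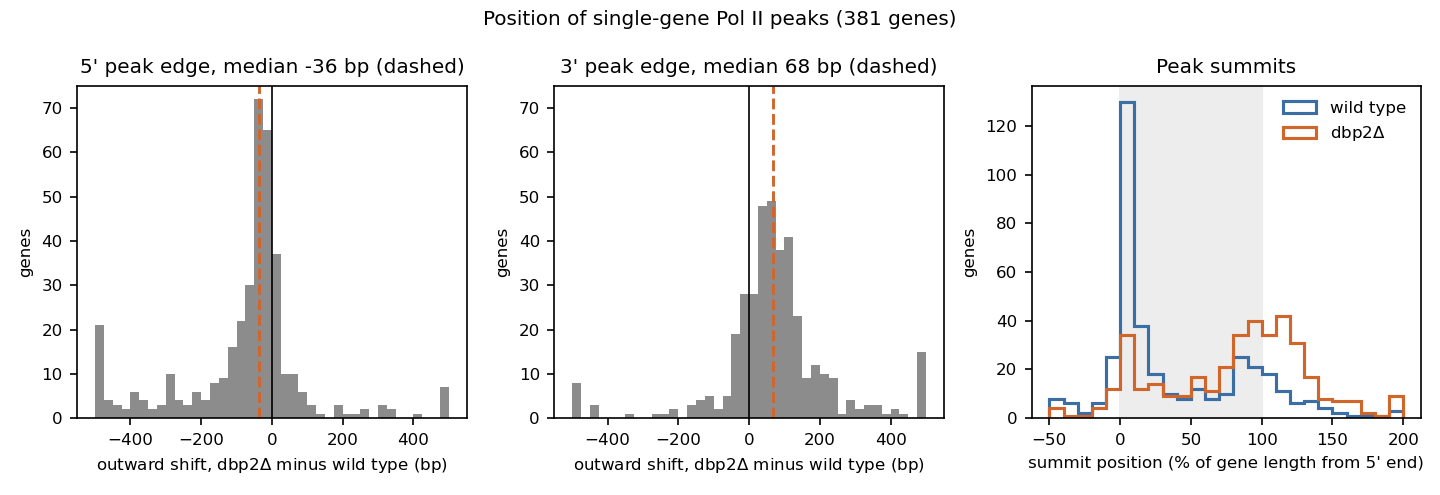
Number of genes by outward difference of the 5′ and the 3′ peak edge (bp, dbp2Δ minus wild type, values beyond 500 bp placed in the last bin, dashed line at the median of -36 or 68 bp) and by summit position (% of gene length, gene body shaded) in both strains. In the wild type most summits lay in the part of the gene next to the 5′ end, and in dbp2Δ most lay around the 3′ end.

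The largest downstream differences of the 3′ edge belonged to ALA1 (1881 bp), OCH1 (1345 bp), RRN3 (1283 bp), RPO21 (1247 bp) and CCT8 (1218 bp). ALA1 encodes alanyl-tRNA synthetase, RRN3 a Pol I initiation factor, RPO21 the largest Pol II subunit and CCT8 a chaperonin subunit. In these 5 genes the wild-type peak ended inside the gene and the dbp2Δ peak past its end. At RPO21 the wild-type list held another, separate peak over the 3′ end of the gene, so the difference there reflects a peak that was split in the wild type only. Another peak over part of the gene was found for 22 of the 381 genes, in either list. The largest upstream differences belonged to MTR4 (-1748 bp), LEU9 (-1224 bp), ADE3 (-1189 bp), TSA1 (-849 bp) and STD1 (-701 bp). In MTR4, LEU9, ADE3 and STD1 the dbp2Δ peak ended inside the gene. Such values depend on where the caller split or ended a peak, and they are the extremes of each direction rather than typical genes.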

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

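Of the values below, those for peaks of at least 290 bp, peaks joined within 500 bp, the correction for fragment length, the snoRNA genes, genes without another peak and the summit differences were chosen after the data were seen, the snoRNA genes and distant neighbours before their own values were, and all other values before the data. Of 878 alternative values, 776 stayed in the range of the first value, 102 moved and 0 reversed. Counts and shares cannot change sign, so only the edge and summit differences could have reversed. Of the 878 values, 672 were counts for other gene groups, of which 608 stayed within 1.5 times the first value and 64 moved. These totals therefore say little on how firm the main differences are. With peaks of at least 2-fold enrichment there were 815 wild-type and 843 dbp2Δ peaks, fewer by construction. Of these, 84.8% and 81.6% were shared and 124 and 155 were not. The phosphate genes then numbered 3 with a wild-type peak and 2 in the wild type only, and 2 tRNA genes were wild-type-only. With the same number of highest-fold peaks per list, 80.9% of the dbp2Δ peaks were shared and 1 tRNA gene was wild-type-only. Peaks of at least 290 bp left 84.4% of the wild-type peaks shared, and joining within 500 bp left 1 tRNA gene wild-type-only. With any overlap, 2460 wild-type and 2698 dbp2Δ genes had a peak, 300 and 538 of them in 1 strain only, with 8 phosphate genes and 1 tRNA gene wild-type-only. Overlap of at least 50% of the peak gave 77.8% and 71.5% shared, and of at least 50% of both peaks 57.9% and 58.4%. The 3′ edge difference was 54 bp and the 5′ difference -30 bp for peaks that overlapped no other gene, 84 bp at convergent and 51 bp at tandem neighbours, 33 bp at snoRNA genes, and 53 and -51 bp after correction for fragment length. The summit difference was 42.8% of gene length where the next downstream gene lay at least 500 bp away, 14.5% (3.70 to 33.3) for peaks that overlapped no other gene, and 10.6% for peaks of at least 3-fold enrichment outside the ribosomal protein genes. Without the 22 genes that another peak also overlapped, the differences were 67 and -36 bp at the edges and 21.7% at the summit. Beyond 50 bp, 58.0% of genes had the 3′ edge downstream, 41.2% the 5′ edge inward and 10.5% outward. Beyond 200 bp, 13.4% had the 3′ edge downstream, 4.20% upstream, and 17.8% the 5′ edge inward. Except where the construction shows it, the cause was not tested. Joining peaks less than 200 bp apart left both lists as they were, so it tested nothing. No paired analysis was possible because each list pools its 3 replicates before the peaks were called, and single replicates could not be left out for the same reason. The pooled depth limits which weak peaks were called, and peaks near the threshold in 1 list can be missing from the other for that reason alone.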

Other observations

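The gene families and their loss shares, the chromosome-end peaks, the 5′ edge test, the strong peaks without ribosomal protein genes and all tests of the phosphate genes were chosen after the results were seen. The snoRNA genes, the genes with a distant neighbour and the strong peaks were added after the downstream position was seen, but before their own values were. Purine synthesis genes had a peak for 10 of 11 members in the wild type and 7 in dbp2Δ, the difference being ADE17 (fold enrichment 4.77 in the wild type), ADE12 (4.97) and ADE2 (2.11), so that 30.0% of those with a wild-type peak had none in dbp2Δ, against 15.0% of all protein-coding genes with one. Pyrimidine synthesis genes had 6 of 9 and 3 of 9, with URA1, URA6 (1.76) and URA4 (2.41) in the wild type only (50%). Inositol and phospholipid genes had 7 of 11 and 4 of 11, with CDS1 (1.63), CHO2 (3.93) and ACC1 (3.41) in the wild type only (42.9%). Proteasome genes had 24 of 34 and 21 of 34, with RPN12, PRE3, RPN13, PRE8 and PRE10 in the wild type only (20.8%) and RPT1 and PRE5 in dbp2Δ only. Random lists matched on wild-type fold enrichment lost as many in 11.6%, 3.91%, 4.81% and 57.8% of draws for these 4 families, which were picked from 15 after their values were seen. Of their 14 wild-type-only genes, URA1, CDS1, PRE3 and RPN13 had 0% covered in dbp2Δ, and the other 10 were partly covered, over 4.25% to 42.8%. Of the 14, 11 lay under wild-type peaks that overlapped a dbp2Δ peak, and for 7 the summit of the highest peak was outside the gene. The peak over RPN13 was that of URA4, the fold enrichment given for CHO2 was that of the peak over CYS4, which had a peak in both lists, and the peak over ACC1 covered 3 genes, so these values do not describe lost peaks of the genes themselves.

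Other families differed by at most 2 genes in either direction. Aminoacyl-tRNA synthetase genes had a peak for 18 of 20 and 17 of 20, vacuolar ATPase genes for 12 of 16 and 13 of 16, chaperonin genes for 6 of 8 and 7 of 8, RNA exosome genes for 7 of 12 in both, ergosterol genes for 9 of 20 in both and cleavage and termination factor genes for 4 of 18 in both. Mitochondrial ribosomal protein genes had 11 of 56 and 10 of 56, mitochondrial ATP synthase genes 6 of 19 and 5 of 19, cytochrome c oxidase genes 5 of 20 and 4 of 20, nuclear pore genes 1 of 21 and 3 of 21, and thiamine genes 0 of 16 in both. The telomerase RNA gene TLC1 (chromosome II, 307587 to 308887) was 100% covered in the wild type (4.76) and 26.1% in dbp2Δ. It is the only gene of its kind and was named outside the rule for named genes. Within 5000 bp of a chromosome end the wild type had 1 peak, over IRC7, and dbp2Δ had 12. Of these 12, the peak over IRC7 was shared and 11 had no wild-type counterpart. Several of the 11 lay over the repeated Y′ helicase genes YRF1-1, YRF1-2, YRF1-5 and YRF1-8, with fold enrichments from 1.28 to 1.87, and reads from such repeats cannot be assigned to 1 copy.

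The downstream position of peaks in dbp2Δ was weighed against technical explanations. Longer fragments or greater depth would move both edges outward, but the 5′ edge moved by -36 bp (-44 to -31), inward. In 88 genes whose downstream neighbour lay at least 500 bp away, the median summit difference was 42.8% of gene length (11.4 to 80.6). This cannot exclude signal of the next gene, because the dbp2Δ peaks of these genes ended a median of 528.5 bp past the gene. In 92 genes whose peaks overlapped no other gene the difference was 14.5% (3.70 to 33.3). That argues against neighbouring signal as the whole cause in these 92 genes, and it stays open as a part of the larger values. Noise in flat peaks is argued against by 40.2% (11.3 to 77.6) in 118 genes with at least 3-fold enrichment in both lists. In the 67 of them outside the ribosomal protein genes the difference was 10.6% (4.31 to 26.5). Whether snoRNA genes are spared stays open: the 3′ edge lay 33 bp (9 to 87) downstream at 11 of them, but the bound above 0 set beforehand made no allowance for fragment length, and without its 15 bp per edge the interval is -6 to 72, while the 5′ edge moved by -3 bp (-36 to 46). A hypothesis is that Pol II may be released later, or may dwell longer near gene ends, without Dbp2, but this was not tested: signal past gene ends in each replicate would be needed, and the pooled lists leave a difference between preparations open.

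The larger number of tRNA genes with a peak in dbp2Δ was weighed in the same way. With the same number of highest-fold peaks per list, 61 tRNA genes in dbp2Δ and 33 in the wild type were covered, a ratio of 1.85. The gain therefore did not rest on the weakest peaks. A more permissive call stays open, because the full lists already held similar numbers of peaks (1642 and 1628). Equal numbers do not offset wider peaks, with median widths of 886 bp in the wild type and 988.5 bp in dbp2Δ. Spread from a neighbouring gene stays open, since the summit lay within 150 bp for 66.7% of the 30 gained genes, with a Wilson interval of 48.8 to 80.8 that includes 50%. Recovery of Pol III genes as a class cannot be told apart, because 0 of 5 other Pol III genes overlapped a peak in dbp2Δ only and 5 genes are too few to decide. Reads shared between tRNA gene copies were not tested, as their assignment is not given, and a biological effect of Dbp2 at tRNA genes is only one of several open explanations.

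The missing peaks of phosphate-starvation genes were weighed against chance and the calling threshold. Of random lists matched on wild-type fold enrichment, 0.19% lost as many genes, and in 1.01% of shuffles any of the 17 planned groups with a wild-type peak was as extreme, which argues against a chance choice of genes with peaks of this height. Both comparisons treat genes as independent. They cannot address a difference between cultures or preparations that moves genes regulated together. With peaks of at least 2-fold enrichment the loss was 2 of 3 genes, which was not compared with random lists. The 5 lost genes had a median wild-type fold enrichment of 1.95, from 1.65 to 5.35, and the lowest lay under the upper quartile of wild-type-only peaks (1.75), so a contribution of the threshold stays open for the weaker members. For SPL2 and PHM6 the loss also depends on where a peak with its summit outside the gene ended, and 0.76% of matched lists held as many genes as the 3 whose peak had no counterpart. A candidate explanation is a weaker phosphate-starvation response in dbp2Δ, or a difference in phosphate between the cultures, and neither was tested.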
